A study of Mus musculus with 12 samples.

How the data were processed

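Gene expression was measured by RNA sequencing in 12 libraries of primary mouse hepatocytes. The cells were labelled wild type (WT) or Hnf4a knockout (KO), and each genotype received DMSO vehicle or MJ041, with 3 libraries in each of the 4 groups. HNF4A is the nuclear receptor that maintains hepatocyte identity, and MJ041 is known here only by its code name. The labels give neither its dose nor the time of treatment. They give no statement that the replicates come from separate animals, so the p-values measure only the spread between samples.

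The deposited table holds raw counts of reads per Ensembl gene, which the authors left without normalization. RNA was extracted with a column kit and made into stranded libraries that were read on an Element AVITI sequencer. The submitters' processing notes name FastQC, Trimmomatic 0.34, STAR 2.7.10b, featureCounts and DESeq2, with the mouse genome mm39. They do not state the strand or multimapping settings of the counting, so counts of close paralogs may share reads in a way that cannot be checked here. The annotation at hand belongs to another genome build and was used only for gene symbols, so no coordinates are given. A symbol was found for 52081 of the 55414 gene identifiers, and for 14885 of the 14919 genes tested. Genes without a symbol held at most 0.274% of a library's counts.

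The libraries held between 16740761 and 17902832 counts. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules. A group at 0 was set to a floor of 3 counts over the group. For a group with 1 to 3 counts, the ratio is given with its exact 95% interval in place of a fitted fold change. Pairs of libraries within a group had a chi-square per degree of freedom between 4.62 and 15.5 across genes, which is above the value of sequencing noise alone, so no pair is a repeated reading of 1 library.

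Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by edgeR's filterByExpr with its minimum count of 10, and libraries were scaled by TMM. A quasi-likelihood model with 1 coefficient per group was fitted to all 12 libraries. Adjusted p-values are Benjamini-Hochberg values over all tested genes, with a threshold of 0.05. The comparisons were KO against WT with vehicle, MJ041 against vehicle in WT, MJ041 against vehicle in KO, the interaction (the MJ041 response in KO minus that in WT), KO against WT with MJ041, and the MJ041 response averaged over genotypes. CPM is a count scaled to a common library total in the usual unit of that name, and levels are means with the standard deviation (SD) over 3 libraries. Log2 fold changes come from edgeR. Their standard error (SE) is the size of the log2 fold change divided by the square root of its F statistic. That statistic rests on the fit to all 12 libraries, and n = 3 beside an SE is the number of libraries per group.

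There were 40 gene lists of pathways and cell types, and 38 of them had at least 5 tested members. The list of lymphocyte and neutrophil markers had 4 tested members and that of erythroid markers had 2, so these were not tested. Each list was compared with the other genes by limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. In this fit no list in any of the 6 comparisons passed when camera estimated that correlation from each list's own members. The limma test fry was run beside it, which asks whether a list's genes move, on balance, one way without setting them against other genes. Where a count within a list is said to be adjusted over the list alone, only the list's members entered the adjustment.

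The groups, comparisons, gene lists, most alternatives and the rule for naming genes were chosen before the data were examined. The rule names Hnf4a. It adds the 6 largest rises and 6 largest falls among genes with an adjusted p below 0.05, a mean of at least 5 CPM in the higher group, no overlap between the libraries of the groups compared, and a symbol that is not a predicted gene. With 3 libraries against 3, 10% of unchanged genes show no overlap by chance. For each list described, the rule takes the 3 tested members with the smallest adjusted p among those that passed, or the 2 members with the highest mean where none passed. At most 12 called lists are described per comparison, besides the regulators and cell types chosen in advance. Genes named outside this rule were chosen after their values were seen, and the text says which. Some genes that the rule takes are not reported here.

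The same fit was tested on simulated data with known changes in 3 sizes. Only genes with a mean of at least 5 CPM were changed. Counts were drawn independently for each gene, without the structure shared across genes, such as cell content, that the real libraries hold. For KO against WT with vehicle it recovered 83.6% of 1.5-fold changes and 95.5% of 2-fold changes. For MJ041 it recovered 79.1% and 89.6% of these in WT, and 86.6% and 94.0% in KO. For the interaction it recovered 47.8% and 85.1%, and all comparisons recovered at least 98.5% of 4-fold changes. Between 7 and 13 unchanged genes were called in each comparison. These values do not carry over to real libraries with such shared structure, nor to genes of lower level.

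The alternatives were DESeq2, limma voom, RLE or no scaling factors in place of TMM, no filter or a stricter filter, a replicate block, only the 2 groups compared, other thresholds, and each library left out in turn. Chosen after seeing the data were voom with a weight per library, the mean level of 3 non-hepatocyte marker lists (Kupffer cells, endothelial cells and stellate cells) as a covariate, and a fit without the 2 MJ041-treated WT libraries lowest in stellate markers. Counts per exon and splicing were not analysed here.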

Results

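RNA was sequenced from primary mouse hepatocytes, the main parenchymal cells of the liver, in culture. WT and Hnf4a KO cells were treated with DMSO vehicle or with MJ041, and each of the 4 groups held 3 libraries. The libraries ranged from 16740761 counts (KO with MJ041, replicate 1) to 17902832 counts (WT with vehicle, replicate 3). The title of the series places the study in work on HNF4A dysfunction in sepsis. Genotype separated the libraries along the first principal component, which held 73.3% of the variance. The second component held 10.3% and separated WT libraries from each other. On it the MJ041-treated WT libraries lay at -42.9, -34.6 and 11.7 and the vehicle-treated ones at 25.1, 3.64 and 36.6. Albumin (Alb), the most abundant transcript of each WT and each KO library, took between 4.41% and 5.30% of the counts in WT and between 1.83% and 2.05% in KO.

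The first comparison asked how cells labelled Hnf4a KO differed from WT cells with vehicle. Many hepatocyte genes fell in KO cells, and genes of cell division rose. F12 (ENSMUSG00000021492), coagulation factor XII, fell from 181 to 5.45 CPM, a log2 fold change of -5.05 ± 0.09 (SE, n = 3). Ccnd1, which encodes cyclin D1 of the G1 phase, rose from 46.7 to 363 CPM, a log2 fold change of 2.96 ± 0.09. Hnf4a itself (ENSMUSG00000017950) fell from 124 ± 12.6 to 65.1 ± 3.57 CPM (SD, n = 3), a log2 fold change of -0.92 ± 0.10 with an adjusted p of 8.9e-06. Its counts in KO cells thus stayed at 52.7% of the WT level. The labels do not say which exons were deleted.

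**Figure D1:**
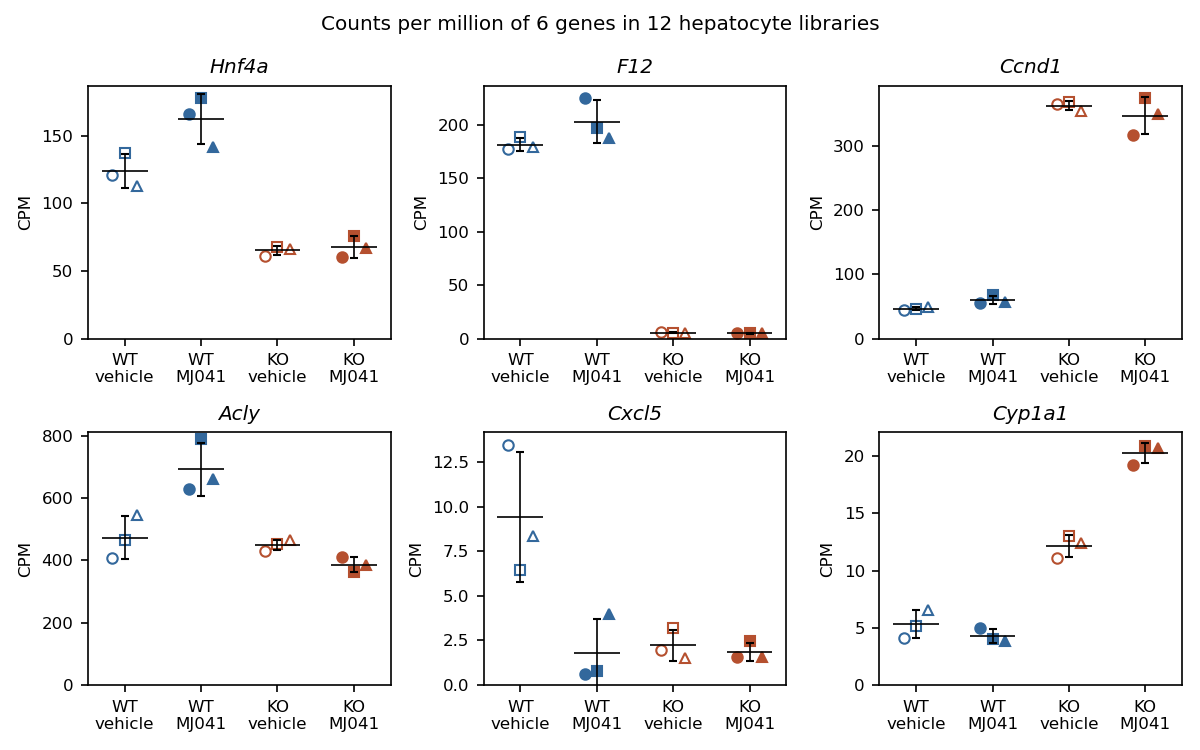
Normalised counts (CPM) of Hnf4a, F12, Ccnd1, Acly, Cxcl5 and Cyp1a1 in each of the 12 libraries, by group. Points are libraries with a shape per replicate number, lines are group means and bars are the SD (n = 3), drawn down to 0 at most; F12 had a mean of 181 CPM in vehicle-treated WT and 5.45 CPM in vehicle-treated KO libraries.

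Of 46 tested HNF4A target genes, 34 fell and 6 rose, in both the adjustment over all genes and that adjusted over the list alone, with a median log2 fold change of -2.16 (adjusted p = 4.1e-09 by camera; adjusted p = 0.50 with an estimated correlation). Beside F12, the fibrin-stabilising factor subunit F13b (-4.94) and the apolipoprotein Apom (-4.90) fell. Among 30 genes of lipoproteins and lipid export, 18 fell and 5 rose (18 and 6 when adjusted over the list alone), with a median of -0.48 (adjusted p = 0.50 with an estimated correlation). Apoa2, an apolipoprotein of HDL, fell from 1769.5 to 13.8 CPM, and Apoc3, an inhibitor of triglyceride clearance, fell by 2.85 on the log2 scale. The urea cycle and amino acid list had 33 falls and 9 rises among 48 members, with a median of -0.73 (adjusted p = 0.60 with an estimated correlation). Otc, the ornithine transcarbamylase of the urea cycle, changed by -5.76, Haao of tryptophan breakdown by -6.54 and Gnmt of methionine metabolism by -2.84.

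Drug-metabolising enzymes fell in large part. Of 44 constitutive cytochrome P450 and phase II genes, 25 fell and 10 rose, with a median of -1.76 (adjusted p = 0.50 with an estimated correlation). They included Cyp2c67 (-6.38), Cyp2j5 (-6.21) and Ugt3a2 (-6.43). Among 40 genes regulated by the xenobiotic receptors CAR and PXR, 24 fell and 10 rose, with a median of -0.73 (adjusted p = 0.50 with an estimated correlation), and Cyp2c50 fell by 7.71. Among the largest falls overall were Cyp2c69 (-10.89) and the carboxylesterase Ces3a (-8.36). Some genes were nearly absent from KO libraries. Cyp2c54 had 2471 counts over the 3 WT libraries and 1 over the 3 KO libraries, a ratio of 2480 (95% interval 445 to 97996). The sulfotransferase Sult2a8 had 1981 and 1 counts, a ratio of 1988 (interval 356 to 78571). Ces3b had 966 and 1, a ratio of 970 (interval 174 to 38334), and Cyp2c38 had 647 and 2, a ratio of 325 (interval 89.5 to 2687). The Cyp2c and Gstm genes are close paralogs, and reads shared among them could not be separated here.

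Genes of proliferation and of the cytoskeleton rose. Of 42 cell cycle genes, 38 rose and 1 fell (40 and 1 when adjusted over the list alone), with a median of 2.20 (adjusted p = 0.50 with an estimated correlation). Anln of cytokinesis rose by 3.18 on the log2 scale and the mitotic motor gene Kif11 by 3.60. Among 38 cytoskeleton and adhesion genes, 24 rose and 6 fell, with a median of 0.33 (adjusted p = 0.50 with an estimated correlation). They included the actin-binding Cnn2 (3.00) and Csrp1 (1.61) and the tropomyosin Tpm2 (6.71). Other large rises were those of Uts2b (7.46), the calcium channel gene Cacna1h (7.07), Mab21l3 (6.54) and Igdcc4 (6.28). Pnliprp1, a lipase-related gene, had 0 counts in vehicle-treated WT libraries and 1888 in vehicle-treated KO libraries, which is at least 627-fold higher against a floor of 3 counts over the group. The 12 tested cholangiocyte markers, which belong to bile duct cells, had 7 rises and 1 fall (7 and 3 when adjusted over the list alone), with a median of 0.99 (adjusted p = 0.50 with an estimated correlation). Krt19 rose by 3.27, Bicc1 by 2.66 and Tspan8 by 5.17.

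Ribosomal protein genes rose, 45 of 47 with a median of 0.41 (adjusted p = 0.50 with an estimated correlation), among them Rpl26 (2.49), Rps18 (0.62) and Rpl15 (0.55). Respiratory chain genes did so too, 38 of 45 with a median of 0.30 (adjusted p = 0.51 with an estimated correlation), among them Ndufa1 (0.75), Atp5c1 (0.59) and Ndufs1 (0.49). Endoplasmic reticulum chaperone genes rose in 20 of 25 cases and fell in 1, with a median of 0.82 (adjusted p = 0.72 with an estimated correlation). Pdia4 (1.47) and Sec61b (0.82) rose, while Xbp1, which encodes a transcription factor that induces such genes, fell (-0.67). Of 34 genes of the integrated stress response, the ATF4 programme of amino acid supply, 21 fell and 6 rose, with a median of -0.43 (adjusted p = 0.50 with an estimated correlation). Asns (-1.12), Mthfd2 (-0.99) and Slc3a2 (-0.88) were among the falls. Targets of the dioxin receptor AHR rose in 11 of 15 cases and fell in 2, with a median of 0.97 (adjusted p = 0.50 with an estimated correlation), among them Gstm3 (5.68), Ugt1a6b (2.15) and Htatip2 (1.45). NRF2 targets, which serve antioxidant defence, rose in 21 of 38 cases and fell in 8, with a median of 0.31 (adjusted p = 0.82 with an estimated correlation). Aox1 (1.83) and Cbr3 (2.62) were among the rises, and the call on the NRF2 list was lost without vehicle-treated KO replicate 2.

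Several lists were not called. Hepatocyte transcription factors went both ways, with 14 rises and 9 falls among 29 members, such as Onecut2 (1.38) and the CAR gene Nr1i3 (-4.23). Markers of Kupffer cells had 2 rises and 1 fall among 20 members, those of endothelial cells 1 rise and 1 fall among 21, and those of stellate cells 4 rises and 3 falls among 17. Mpeg1 of macrophages rose by 1.10 and Vsig4 by 1.25, while Cd68 changed by -0.66. In the endothelial list Flt4 rose by 0.25 and Tek changed by -1.14. In the stellate list Tagln rose by 1.23, Reln by 1.76 and Angptl6 by 0.99.

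**Figure D2:**
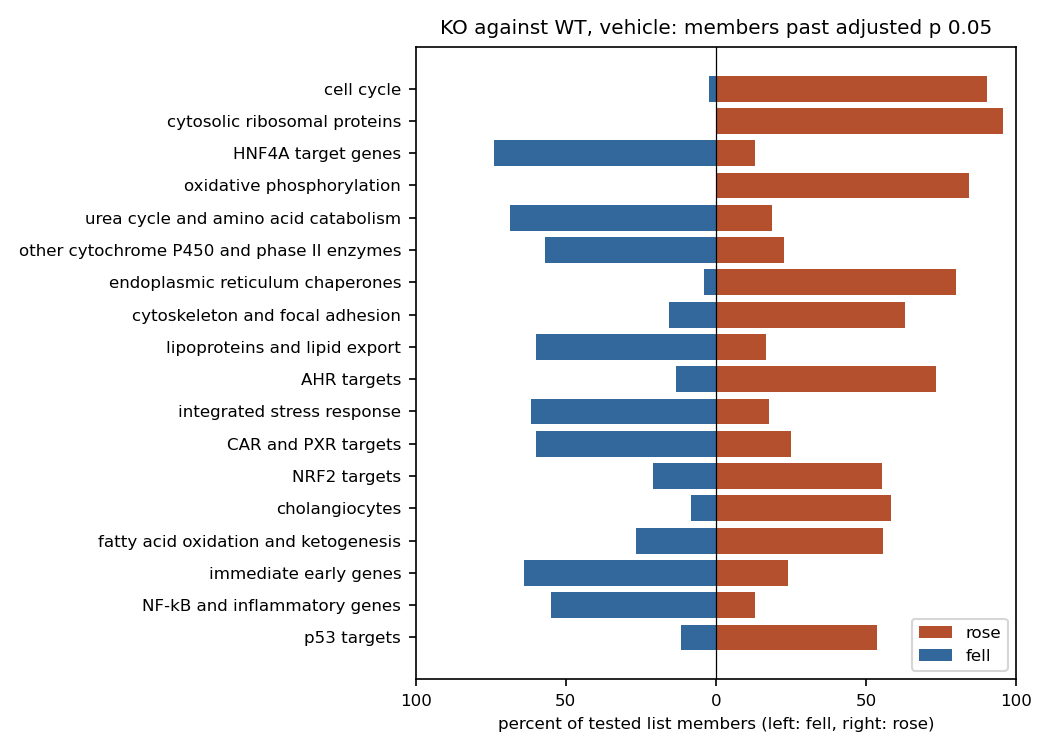
Percent of the tested members of each called gene list that rose or fell in KO against WT cells with vehicle, for the 18 lists that camera called. Bars to each side are members with an adjusted p below the threshold in edgeR; in the cell cycle list 38 of 42 members rose and in the HNF4A target list 34 of 46 fell.

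In all, edgeR called 8126 of 14919 tested genes in KO against WT with vehicle, 4108 up and 4018 down, and 2265 of them changed at least 2-fold. Camera called 18 lists, and none passed with an estimated correlation. Fry, which does not set a list against other genes, called 26 of the 38 lists.

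The next comparison asked what MJ041 did to WT cells. Some genes of sugar use and fat synthesis rose (8 of 35 and 7 of 27 tested), and some inflammatory and interferon-induced genes fell (8 of 31 and 19 of 41). Acly, the ATP citrate lyase that supplies acetyl-CoA for fat synthesis, rose from 472 ± 69.3 to 693 ± 85.2 CPM (SD, n = 3), a log2 fold change of 0.55 ± 0.10 (SE) with an adjusted p of 0.032. The neutrophil-attracting chemokines Cxcl3 (-2.70) and Cxcl5 (-2.38) fell. Hnf4a had 124 CPM with vehicle and 162 CPM with MJ041, a log2 fold change of 0.39 ± 0.10 that did not pass (adjusted p = 0.062). Large rises were those of Ccdc68 (1.27), Klhdc7a (1.20), the tight junction gene Cldn4 (1.16) and the DNA repair gene Nbn (1.10). Further large falls were the growth factor gene Ereg (-2.26), the integrin Itga2 (-1.99), Traf1 (-1.88) and Serpinb2 (-1.64).

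Lipogenesis genes rose in 7 of 27 cases, and in 20 when adjusted over the list alone, with a median log2 fold change of 0.43 (adjusted p = 7.0e-11 by camera; adjusted p = 0.38 with an estimated correlation). They included Mlxipl (0.63), which encodes the carbohydrate-responsive factor ChREBP, and Tkfc of fructose metabolism (0.78). Cholesterol synthesis genes rose in 5 of 25 cases, and in 16 when adjusted over the list alone, with a median of 0.32 (adjusted p = 0.50 with an estimated correlation). Sqle (0.49) and Pmvk (0.42) were among them. Glucose and glycogen genes rose in 8 of 35 cases, and in 17 when adjusted over the list alone, with a median of 0.34 (adjusted p = 0.52 with an estimated correlation), and Khk, the ketohexokinase that starts fructose use, rose by 0.44. None of the lipogenesis, cholesterol and glucose genes fell.

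Interferon response genes fell in 19 of 41 cases, and in 39 when adjusted over the list alone, with a median of -0.60 (adjusted p = 8.3e-26 by camera; adjusted p = 0.50 with an estimated correlation). Gbp7 (-0.71), Zbp1 (-0.70) and Gbp2 (-0.67) were among them. NF-kB and inflammatory genes fell in 8 of 31 cases, and in 24 when adjusted over the list alone, with a median of -0.68 (adjusted p = 0.38 with an estimated correlation). Here the cytokine gene Il6 changed by -3.56 and the chemokine gene Ccl7 by -1.42. Immediate early genes, which can also respond to cell handling, were called as lower too, with a median of -0.11 (adjusted p = 0.025 by camera; adjusted p = 0.55 with an estimated correlation). Of 25 members 0 passed over all genes, and 7 passed as lower and 1 as higher when adjusted over the list alone. This list is described outside the rule, after its values were seen, and its call was lost without vehicle-treated WT replicate 3 or MJ041-treated WT replicate 2, with the marker covariate and without the 2 WT libraries low in stellate markers. Markers of other liver cells were also lower in WT libraries with MJ041. The stellate list stood at 0.940, 0.949 and 2.06 mean log2 CPM with MJ041 and at 2.04, 1.99 and 2.03 with vehicle. Kupffer markers stood at 1.24, 2.28 and 3.63 against 3.02, 2.58 and 3.99, and endothelial markers at 2.24, 2.37 and 3.44 against 3.32, 2.94 and 3.93. Camera called these lists at medians of -0.67, -0.64 and -0.78 (adjusted p = 0.52, 0.55 and 0.54 with an estimated correlation), with no member passing over all genes. When adjusted over the list alone, 8 of 17 stellate markers passed as lower and 1 as higher, 3 of 21 endothelial markers passed as lower, and 0 of 20 Kupffer markers passed. Their most abundant members were Ecm1 (-0.67), Cxcl12 (-0.41), Mpeg1 (-0.73), Cd68 (0.03), Stab1 (-0.57) and Flt4 (0.08). The matrix list had 3 falls and 1 rise among 33 members, with a median of -0.40 (adjusted p = 0.52 with an estimated correlation), and Lamb1 (-1.48) and Tnc (-1.44) fell while Fn1 rose (0.56). For antigen presentation 1 of 21 members, Psmb9 (-0.60), fell, with a median of -0.26 (adjusted p = 0.52 with an estimated correlation).

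**Figure D3:**
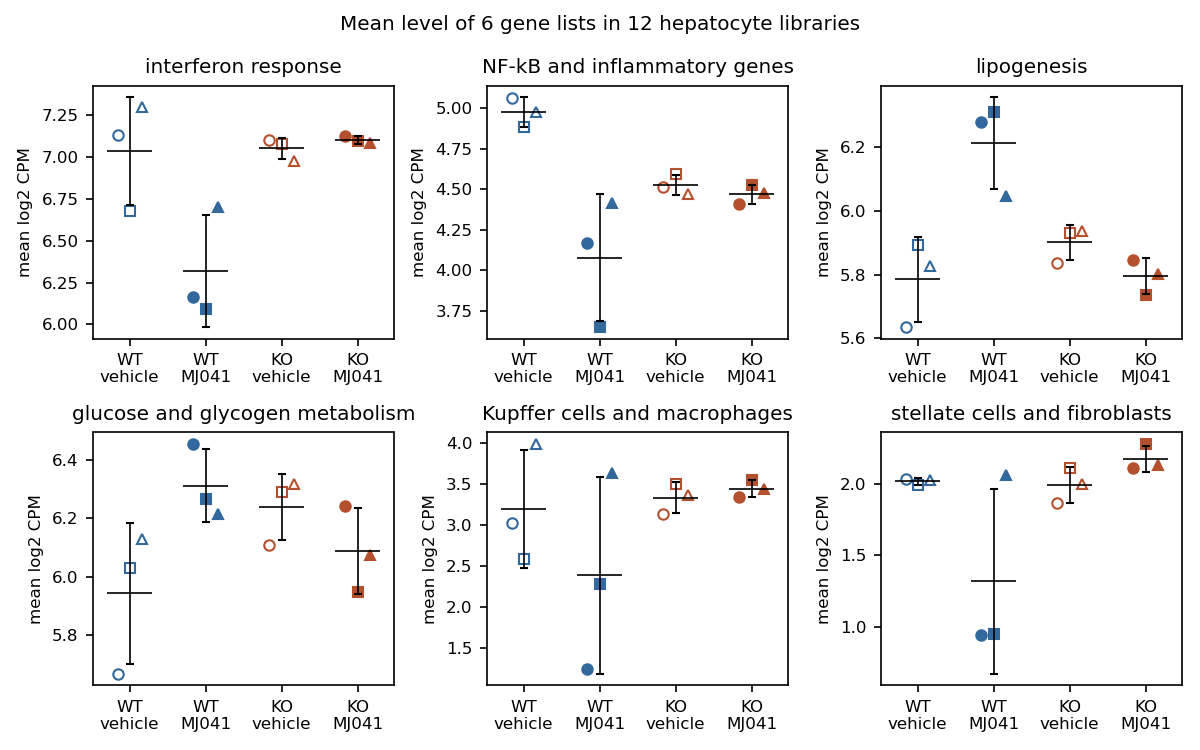
Mean log2 CPM of the members of 6 gene lists (interferon response, NF-kB and inflammatory genes, lipogenesis, glucose and glycogen metabolism, Kupffer cells, stellate cells) in each of the 12 libraries. Points are libraries with a shape per replicate number, lines are group means and bars are the SD (n = 3); in the stellate list 2 of the 3 WT libraries with MJ041 lie at 0.940 and 0.949, below the 3 with vehicle (1.99 to 2.04).

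Among HNF4A target genes, 3 of 46 rose, among them Mttp of lipoprotein assembly (0.64) and the glucose transporter Slc2a2 (0.88), with a median of 0.18 (adjusted p = 0.55 with an estimated correlation). With the non-hepatocyte markers as a covariate the HNF4A target median was 0.06 and without the 2 WT libraries low in stellate markers, which leaves 1 treated library, it was 0.02, and camera did not call it in either (adjusted p = 0.093 and 0.20). Respiratory chain genes had a median of 0.11 with no member passing (adjusted p = 0.52 with an estimated correlation), as for Atp5b (0.12) and Atp5a1 (0.13). Of 47 ribosomal genes 1 rose, Rpl3 (0.34), with a median of 0.14 (adjusted p = 0.52 with an estimated correlation). The fatty acid oxidation list had 2 rises among 45 members, Acadvl (0.33) and Hsd17b4 (0.30), with a median of 0.19 (adjusted p = 0.55 with an estimated correlation). In the NRF2 list 5 of 38 rose, among them Me1 (0.48), Tkt (0.49) and Ephx1 (0.60), with a median of 0.15 (adjusted p = 0.58 with an estimated correlation). The integrated stress response list had 4 rises among 34, with a median of 0.12 (adjusted p = 0.50 with an estimated correlation), including Chac1 (0.85), Psat1 (0.31) and Phgdh (0.69). CAR and PXR targets had 2 rises among 40, Aldh1a7 (0.54) and Gstm1 (0.70), with a median of 0.21 (adjusted p = 0.55 with an estimated correlation). Hepatocyte transcription factors had 1 rise among 29, Esrra (0.31), with a median of 0.15 (adjusted p = 0.52 with an estimated correlation). The AHR and cholangiocyte lists were not called, and Htatip2 rose in the first (0.78) and Cldn4 in the second. The calls on the HNF4A target, NRF2, CAR and PXR, hepatocyte transcription factor and Kupffer lists were lost without MJ041-treated WT replicate 1. Those on the CAR and PXR and transcription factor lists were also lost without vehicle-treated WT replicate 1, and that on the Kupffer list without vehicle-treated WT replicate 3.

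In WT cells edgeR called 329 genes with MJ041, 177 up and 152 down, and 79 changed at least 2-fold. At an unadjusted p below 0.05 there were 3219 genes, against 746 by chance. Camera called 24 lists. The gene count rested on single libraries, although the smallest adjusted p was 0.029. Without a vehicle-treated WT replicate it was 0 (replicate 1), 574 (replicate 2) or 31 (replicate 3), and without an MJ041-treated WT replicate 49 (replicate 1), 0 (replicate 2) or 2059 (replicate 3). Leaving out a KO library with vehicle gave 0 (replicate 1), 108 (replicate 2) or 0 (replicate 3), and one with MJ041 gave 210 (replicate 1), 163 (replicate 2) or 0 (replicate 3). With the marker level as a covariate no gene passed in edgeR (1743 at an unadjusted p below 0.05), and none without both WT libraries low in stellate markers (747), a fit that leaves 1 MJ041-treated WT library and assumes that it varies like the other groups. With the 2 WT groups alone none passed either (2561), and DESeq2 called 894 genes and voom 402.

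In KO cells, where the question was whether MJ041 acts in this genotype, no gene passed in edgeR. Acly had a mean of 449 CPM with vehicle and 386 CPM with MJ041, a log2 fold change of -0.22 ± 0.10 (SE, n = 3) with an adjusted p of 1. Hnf4a had 65.1 and 67.5 CPM (0.05 ± 0.10). The lipogenic gene Scd1 (-0.25) did not pass either. Cyp1a1, the classic AHR target, was the only gene called by DESeq2, at a log2 fold change of 0.73 (adjusted p = 0.035), with 12.2 ± 0.957 CPM with vehicle and 20.3 ± 0.909 CPM with MJ041 (SD, n = 3). It is named outside the rule, after its values were seen. The AHR list as a whole was not called in KO, and its abundant members Xdh (-0.01) and Nfe2l2 (0.02) stayed close to 0.

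List medians in KO were small and no member of any list passed over all genes. When adjusted over the list alone, 1 HNF4A target and 1 glucose gene passed as lower and 1 AHR target as higher. Camera called glucose and glycogen genes (-0.12), lipogenesis (-0.12), other cytochrome P450 and phase II enzymes (-0.09), cholesterol synthesis (-0.07), HNF4A targets (-0.06) and hypoxia response (-0.13) as lower. The adjusted p = 0.91 with an estimated correlation holds for each of these 6 lists. Examples are Ldha (-0.06), Ces1c (-0.02), Ugt2b34 (0.01), Apob (0.03) and Eno1 (-0.08). The integrated stress response list was called as lower (-0.04, adjusted p = 0.90 with an estimated correlation), as for Nars (-0.05) and Slc3a2 (0.02). Mitochondrially encoded genes were called as higher (0.15, adjusted p = 0.90 with an estimated correlation), with mt-Co1 at 0.15 and mt-Nd1 at 0.11. Called as higher were also the cell cycle (0.12), cytoskeleton (0.05) and respiratory chain (0.04) lists, each with an adjusted p = 0.91 with an estimated correlation. Their abundant members include Mcm6 (0.02), Ccnd1 (-0.06), Actb (0.02), Flna (0.05), Atp5b (0.02) and Atp5a1 (0.01). Lists not called held Onecut2 (-0.26), Rxra (0.03), Gstm1 (0.02), Fth1 (-0.04), Sqstm1 (0.03), Mpeg1 (0.00), Cd68 (-0.06), Flt4 (-0.03), Stab1 (-0.08), Cxcl12 (0.11), Pigr (0.01) and Spp1 (-0.08).

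In edgeR 0 genes passed for MJ041 in KO, with 414 at an unadjusted p below 0.05 against 746 by chance, while DESeq2 called 1 and voom 0. The edgeR fit left differences between KO replicate numbers in its spread, and the 414 lay below chance, so responses may be missed. Camera called 11 lists, and 6 without MJ041-treated KO replicate 2. Without that library the calls on the glucose, lipogenesis, HNF4A target, cytochrome P450, stress response, cytoskeleton and respiratory chain lists were lost, and the hypoxia and cell cycle lists turned to the other direction. Calls were also lost without vehicle-treated KO replicate 1 (stress response, cytoskeleton, and cell cycle with its direction turned), replicate 2 (cholesterol, cytochrome P450, hypoxia) or replicate 3 (cytoskeleton, respiratory chain, hypoxia, cell cycle). Without MJ041-treated KO replicate 1 the cholesterol call was lost, and without replicate 3 the hypoxia and cell cycle calls. The cell cycle call was lost without vehicle-treated WT replicate 3 or MJ041-treated WT replicate 1 as well, and the call on the mitochondrially encoded genes held without any 1 library.

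Whether the response to MJ041 differed between genotypes was tested by the interaction, the response in KO minus that in WT. No single gene passed in edgeR. The lists called included those of sugar, fat and inflammatory genes and of non-hepatocyte markers. Acly had an interaction of -0.77 ± 0.15 (SE, n = 3; adjusted p = 0.12), and Scd1 had -1.10. Lipogenesis had a median interaction of -0.56 (adjusted p = 6.8e-13 by camera; adjusted p = 0.40 with an estimated correlation), and 17 of its 27 members passed as lower when adjusted over the list alone. The glucose and glycogen list had a median of -0.43 with 14 of 35 members lower when adjusted over the list alone (adjusted p = 0.44 with an estimated correlation). Cholesterol synthesis had -0.38 with 13 of 25 lower when adjusted over the list alone (adjusted p = 0.40 with an estimated correlation).

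The interferon response list had a median interaction of 0.75, and 35 of 41 members were higher when adjusted over the list alone (adjusted p = 0.40 with an estimated correlation). Its abundant members Rsad2 and Irf7 had 0.87 and 0.56. The NF-kB list had 0.54 with 11 of 31 higher when adjusted over the list alone (adjusted p = 0.40 with an estimated correlation), and the monocyte chemokine gene Ccl2 had 1.20 and Csf1 0.12. The non-hepatocyte lists moved the same way, with 0.81 for Kupffer, 0.72 for endothelial and 0.68 for stellate markers (adjusted p = 0.55, 0.55 and 0.45 with an estimated correlation). Mpeg1 had 0.74, Stab1 0.50, Ecm1 0.68 and Cxcl12 0.51. The matrix list had 0.66 and the antigen presentation list 0.33 (adjusted p = 0.45 with an estimated correlation for both), with Fn1 at -0.72, H2-K1 at 0.18 and B2m at 0.25. Ribosomal genes had -0.12 (adjusted p = 0.55 with an estimated correlation), as for Rpl4 (-0.18) and Rpsa (-0.06), and the integrated stress response list had -0.16 (adjusted p = 0.40 with an estimated correlation), as for Nars (-0.24).

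HNF4A target genes had a median interaction of -0.27, with 6 of 46 lower when adjusted over the list alone and 0 over all genes. For this list alone camera gave p = 1.8e-05, p = 0.19 with an estimated correlation, and adjusted p = 0.50 with an estimated correlation over the lists. Apob had -0.17 and Hnf4a -0.34 ± 0.15 (adjusted p = 0.33).

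For the interaction edgeR called 0 genes, with 1980 at an unadjusted p below 0.05 against 746 by chance and a smallest adjusted p of 0.12. DESeq2 called 218 and voom 0, and edgeR with a replicate block within genotype also called genes, as given in the part on processing. Without MJ041-treated WT replicate 3 the edgeR count was 852, and without vehicle-treated WT replicate 2 it was 7. Camera called 28 lists, and 13 without MJ041-treated WT replicate 1. Of the lists described, the Kupffer list lost its call without that library and without vehicle-treated WT replicate 3.

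With MJ041 present, KO and WT cells differed much as they did with vehicle. Ccnd1 rose and F12 fell, with log2 fold changes of 2.53 and -5.32. Of 42 cell cycle genes 40 rose and 1 fell, with a median of 2.36 (adjusted p = 0.50 with an estimated correlation). Of 46 HNF4A targets 35 fell and 3 rose (36 and 3 when adjusted over the list alone), with a median of -2.76 (adjusted p = 0.42 with an estimated correlation). Interferon response genes, which were not called with vehicle, rose in 29 of 41 cases and fell in 2, with a median of 0.55 (adjusted p = 0.62 with an estimated correlation). Markers of other cells were higher as well: 7 of 21 endothelial and 7 of 17 stellate markers rose (medians 0.69 and 0.53; adjusted p = 0.71 and 0.62 with an estimated correlation), and the Kupffer list, with 3 rises and 1 fall among 20, had a median of 0.64 and was not called. Lipogenesis genes fell in 17 of 27 cases and rose in 4, with a median of -0.47 (adjusted p = 0.62 with an estimated correlation). In total 8118 genes were called by edgeR, 4005 up and 4113 down, of which 2319 changed at least 2-fold. Camera called 20 lists and fry 29. With library totals in place of TMM factors 4668 genes rose and 3546 fell.

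Averaged over genotypes, no gene was called with MJ041 in edgeR (1729 at an unadjusted p below 0.05), while DESeq2 called 47 and voom 0. A replicate block within genotype gave calls here too, as given in the part on processing. The interferon response list had a median of -0.27 and the NF-kB list -0.34 (adjusted p = 0.72 and 0.69 with an estimated correlation), and lipogenesis had 0.15 (adjusted p = 0.72 with an estimated correlation). Endothelial (-0.43), stellate (-0.28) and Kupffer (-0.23) markers were called as lower too (adjusted p = 0.72, 0.72 and 0.76 with an estimated correlation), with no member passing. When adjusted over the list alone, 31 interferon genes and 19 NF-kB genes passed as lower and 2 lipogenesis genes as higher. These averages do not show a response shared by both genotypes. The interferon and NF-kB medians were -0.60 and -0.68 in WT but 0.06 and -0.05 in KO, where camera called neither list. Lipogenesis had 0.43 in WT and -0.12 in KO. Camera called 17 lists. The edgeR count was 486 without MJ041-treated WT replicate 3 and 2 without vehicle-treated WT replicate 2.

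Across genes, which are not independent replicates, the MJ041 effects in WT and in KO had a Pearson r of -0.0899. No gene was called in both by edgeR, since none was called in KO. The MJ041 effect in WT and the KO effect with vehicle had r = 0.242 across genes. Both share the vehicle-treated WT libraries, and 20 simulations without any effect but with that sharing gave a mean r of 0.490 and at most 0.512. The real and simulated r are not comparable, because real KO effects add a spread that the simulations lack. The covariance of the 2 effects was 0.105 against 0.0346 on average in the simulations (at most 0.0378), which leaves 0.0699. The simulations drew genes independently, so they understate how far the covariance can vary. With the KO effect taken from MJ041-treated cells, which shares the MJ041-treated WT libraries with the opposite sign, r was -0.159 and the covariance -0.0689, against -0.508 and -0.0362 on average in the simulations. In each case the sign was that given by the shared libraries, so no direction of overlap was shown. With the KO effect averaged over vehicle and MJ041, where the shared libraries enter with both signs, r was 0.0424. Of the genes called in both comparisons 97 rose in both (48.7 by chance), 70 fell in both (40.9 by chance), 31 rose with MJ041 and fell in KO (47.7 by chance), and 26 fell with MJ041 and rose in KO (41.9 by chance). These calls share the vehicle-treated WT libraries as well. Cldn4 (1.30), which rose with MJ041 in WT, also rose in KO with vehicle, and Traf1 (-1.59) and Cxcl5 (-2.09) fell in both.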

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

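The counts over other splits of the samples were planned before the results were seen. The tests of other cell content, of library scaling and of leftover WT cells were chosen after the result they address was seen, as were the fits with the marker covariate and without 2 WT libraries.

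In 5 gene lists camera called the MJ041 response in opposite directions in WT and KO cells and also called the difference. The median of the response in KO minus that in WT was -0.56 for lipogenesis (adjusted p = 0.40 with an estimated correlation). It was -0.43 for glucose and glycogen genes (adjusted p = 0.44 with an estimated correlation) and -0.38 for cholesterol synthesis (adjusted p = 0.40 with an estimated correlation). HNF4A target genes had -0.27 (adjusted p = 0.50 with an estimated correlation) and the integrated stress response -0.16 (adjusted p = 0.40 with an estimated correlation). In KO the medians of these lists lay between -0.12 and -0.04 and no member passed in edgeR over all genes. The KO calls on lipogenesis, glucose genes, HNF4A targets and the stress response were lost without MJ041-treated KO replicate 2, that on the stress response also without vehicle-treated KO replicate 1, and that on cholesterol synthesis without vehicle-treated KO replicate 2 or MJ041-treated KO replicate 1. The WT median of the HNF4A targets went from 0.18 to 0.06 with the marker covariate and to 0.02 without the 2 low-marker WT libraries, and its WT call was lost in both and without MJ041-treated WT replicate 1. Apart from the fits without libraries or with library weights, groups of 3 libraries were not searched for samples far from the others.

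The rise of the lipogenesis, cholesterol and glucose lists with MJ041 in WT came with lower markers of non-hepatocytes, and fewer other cells in the treated libraries would raise every hepatocyte transcript alike. The tables argue against this as the whole cause for lipogenesis and glucose genes and leave it open for cholesterol genes: relative to each of 8 other lists made by hepatocytes, lipogenesis was higher by 0.202 ± 0.110 (SE, HNF4A targets) to 0.351 ± 0.0912 and glucose genes by 0.144 ± 0.0528 to 0.293 ± 0.0945, with no overlap between the WT groups and over 2 SE for 7 of the 8 lists each. Cholesterol genes overlapped relative to 3 of the 8 (by 0.0718 ± 0.120 for HNF4A targets), and both these lists and the condition of no overlap with any of them were set after the scores were seen. The 8 lists were themselves higher with MJ041 in WT, with medians from 0.07 (other cytochrome P450 and phase II enzymes) to 0.21 (bile acid genes, CAR and PXR targets). Camera called each as higher except the cytochrome P450 list, and none passed with an estimated correlation. Such a shared rise is what fewer other cells would give. With library totals in place of TMM factors the medians of lipogenesis, glucose and cholesterol genes were 0.37, 0.28 and 0.26. The TMM factors of the WT libraries lay between 0.938 and 1.01, so leaving them out could move these medians only slightly. This fit therefore cannot decide whether another scaling has a part in the rise. Part of the rise goes with the markers and stays open: from 0.43, 0.34 and 0.32 the medians went to 0.26, 0.25 and 0.27 with the marker covariate (fry adjusted p = 0.11, 0.31 and 0.18, from 0.018, 0.064 and 0.032), and to 0.21, 0.17 and 0.17 without the 2 low-marker WT libraries (0.44, 0.86 and 0.76), where 1 treated WT library is left and assumed to vary like the other groups.

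The fall of interferon and NF-kB genes with MJ041 in WT may come from fewer non-hepatocytes, and the tables do not decide this. With the mean level of the Kupffer, endothelial and stellate lists as a covariate, the interferon median was -0.43 (quartiles -0.63 and -0.23) in place of -0.60 (-0.94 and -0.38), and the NF-kB median was -0.51 (-0.84 and -0.35) in place of -0.68 (-1.16 and -0.38). Camera kept both calls (adjusted p = 0.62 and 0.50 with an estimated correlation) and fry in limma lost them (adjusted p = 0.17 and 0.11, from 0.033 and 0.018), but the covariate did not remove cell content: it left the stellate list lower (-0.29) and turned the Kupffer list higher (0.24), both called by camera (adjusted p = 0.64 and 0.66 with an estimated correlation). Without the 2 MJ041-treated WT libraries low in stellate markers the medians were -0.33 and -0.37 (fry adjusted p = 0.76 and 0.018; camera adjusted p = 0.91 and 0.043 with an estimated correlation), in a fit that leaves 1 treated WT library and takes the spread from the other groups. Of the marker lists, 6 of the 17 stellate genes stand on another list and none of the 20 Kupffer or 21 endothelial genes does, and their median levels in vehicle-treated WT libraries were 2.86, 8.49 and 14.9 CPM.

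Hnf4a kept 52.7% of its WT level in vehicle-treated KO libraries. WT cells left among the KO cells would hold every transcript at or above that share, and the tables argue against this as the whole cause. In a first test 16 of 2332 genes with at least 100 CPM in WT kept under 5.27% in every such library (median 1.60%), but the bound set for this test was 20 genes and was missed. A second test, added after that count was seen, took the 41 HNF4A targets with at least 5 CPM, whose library medians lay between 16.2% and 28.0% of the WT level, with 26 of the genes below the Hnf4a share in every library. The list's median log2 fold change of -2.16 in these libraries was already known, so this outcome was fixed and adds no independent support. What argues against leftover WT cells as the whole cause is the level of the 16 genes. Transcripts of the deleted allele that lack only the deleted exons could account for the 52.7% and stay open, since counts per exon were not analysed here.

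Other splits of the same libraries were fitted in the same way. For the comparisons of 6 libraries there are 10 splits, too few for a share under 0.05. In KO against WT with vehicle the real split gave 8126 genes and the highest other 0 (1 split as large), and 18 lists against 20 (2 as large). With MJ041 these were 8118 genes against 0 (1 as large) and 20 lists against 21 (5 as large). For MJ041 in WT they were 329 genes against 582 (2 as large) and 24 lists against 24 (3 as large). The split with 582 genes set vehicle replicates 1 and 3 and MJ041 replicate 3 against the rest. This follows the Kupffer and endothelial marker levels and points to a structure of the samples. It follows the stellate level less well, since vehicle replicate 2 (1.99) lay near the higher libraries (2.03 to 2.06) and far from 0.940 and 0.949. For MJ041 in KO the real split gave 414 genes at an unadjusted p below 0.05 against 2194 (4 as large) and 11 lists against 14 (7 as large). The split with 2194 genes set vehicle replicates 1 and 3 with MJ041 replicate 1 against the rest, several times the real count, so the KO libraries hold a structure other than treatment. That split parts both replicate 1 libraries from both replicate 2 libraries, which lay apart on the third principal component (20.2 and 24.2 against -22.4 and -23.9). For the interaction 100 of 200 splits were drawn. The 28 lists exceeded the highest other split (27) by a margin of 1 list (1 of 100 as large). The split with 27 lists kept the WT groups as they were and exchanged only KO libraries, so a count that high did not need the KO groups. Chance is therefore not excluded for the 28 lists. Nor is it for the 1980 genes at an unadjusted p below 0.05 (highest other 3321, 10 of 100 as large). The 28 lists became 13 without MJ041-treated WT replicate 1, 2 with fry and 0 with an estimated correlation, and the splits take libraries as exchangeable although they hold the structure described above. For the average over genotypes chance cannot be excluded for the 1729 genes (highest other 3467, 15 of 100) or the 17 lists (highest other 28, 38 of 100).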

How the results depend on the processing

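The voom fit with library weights, the marker covariate and the fit without the 2 MJ041-treated WT libraries low in stellate markers, which leaves 1 library assumed to vary like the other groups, were chosen after the data were seen. KO against WT was stable: 8126 genes with vehicle and 8118 with MJ041 stayed within 1.5 times of these counts in all fits at an adjusted p below 0.05 or 0.01, and 2265 and 2319 changed at least 2-fold. MJ041 in WT moved most: 329 genes became 79 at 2-fold, 0 at an adjusted p below 0.01, 894 with DESeq2, 1667 without a filter (more genes tested), 649 with the replicate block, 1943 with the block within genotype, 0 with only the 2 groups, 1557 with weights, 0 with the covariate, 0 without the 2 libraries, and 0 to 2059 without 1 library. For MJ041 in KO the 0 genes became 1 with DESeq2, 15 without a filter and 1 with weights (Cyp1a1). The 0 genes of the interaction became 218, 886, 608 and 1278, and the 0 of the average 47, 523, 335 and 335, with DESeq2, without a filter, with the block within genotype and with weights; without 1 library they ranged from 0 to 852 and from 0 to 486. Lists fell to 0 in all comparisons with an estimated correlation in the reported fit. For KO against WT, fry called 26 lists with vehicle and 29 with MJ041. With fry 5 (WT), 0 (KO), 2 (interaction) and 0 (average) passed, with the covariate 15, 5, 16 and 10, and without the 2 libraries 12 (WT), 12 (interaction) and 7 (average). Without 1 library lists ranged from 15 to 26 in WT, 6 to 14 in KO, 13 to 28 for the interaction and 11 to 19 for the average. The HNF4A list interaction had p = 0.194 with an estimated correlation and 0.0807 with fry. The r between the MJ041 effects was -0.155 with the covariate and -0.113 to -0.0304 without 1 library. The r of the MJ041 and KO effects was 0.0990 with the covariate, 0.0900 without the 2 libraries, 0.0424 with the averaged KO effect, -0.159 with the KO effect in MJ041-treated cells (reversed; -0.508 simulated without effect, from other shared libraries) and 0.205 to 0.326 without 1 library. List directions that reversed had these camera p: for MJ041 in WT, Kupffer 0.00353 with the covariate and 0.00120 without the 2 libraries, and coagulation 0.769, endothelial 0.896 and stellate 0.631 without the 2 libraries; in KO, hypoxia 0.681 (lowest without 1 library 6.6e-07) and cell cycle 0.00762 (lowest 2.0e-18) without MJ041 replicate 2, and cell cycle 0.932 without vehicle replicate 1; for the interaction, Kupffer 0.0146 and endothelial 0.936 with the covariate, 0.0695 and 0.923 without the 2 libraries, and cell cycle 0.656 without MJ041-treated KO replicate 2 (lowest 1.9e-09). Where no construction is named, the cause was not tested. Among named genes 3625 values kept direction and side of the threshold, and 518 lost and 87 gained the call. Another 114 changed sign and had no call in the reported fit. Among lists 1212 kept the call, 296 lost it and 13 reversed. In KO against WT, a list call was lost without single libraries for fatty acid oxidation, NRF2, p53, NF-kB and immediate early genes. The replicate numbers were not taken as pairs, since not every same-number correlation was over 0.1: deviations correlated across genes at -0.0103, 0.203 and 0.499 in WT and at 0.349, 0.458 and 0.0390 in KO. As a hint from the data, KO libraries 1 and 2 do follow their numbers (crossed pairs -0.351 and -0.436). Vehicle replicate 3 in KO correlated best with MJ041 replicate 1 (0.111). However, both KO libraries of replicate 3 lay near the middle of the third principal component (1.47 and 0.145), between those of replicates 1 and 2. The rule of 0.1 thus does not exclude pairing in KO, and the block is given only as an alternative. Genes with up to 3 counts in a group are known only within their counting intervals.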

Other observations

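Beyond the lists above, the proliferation marker Mki67 rose in KO cells with vehicle (log2 fold change 3.58 in edgeR). It was named after its values were seen, as were the genes in this part. Of 26 p53 targets 14 rose and 3 fell (adjusted p = 0.67 with an estimated correlation), and the list call was lost without vehicle-treated WT replicate 1. Of 45 fatty acid oxidation genes 25 rose and 12 fell, with a median of 0.37 and a mean of -0.12 (adjusted p = 0.82 with an estimated correlation), and this call too was lost without vehicle-treated WT replicate 1. NF-kB genes (17 fell, 4 rose; adjusted p = 0.82 with an estimated correlation) and immediate early genes (16 fell, 6 rose; adjusted p = 0.72 with an estimated correlation) were called near the threshold.

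Xist, the X-inactivation transcript, had 1793 CPM in WT and 3096 CPM in KO libraries with vehicle (log2 fold change 0.79, adjusted p = 1.3e-05 in edgeR). The Y-linked genes Ddx3y, Kdm5d and Uty had 0 counts over all libraries and Eif2s3y had 1. In KO libraries the third principal component (4.18% of the variance) separated replicate numbers, with 20.2 and 24.2 for replicate 1, -22.4 and -23.9 for replicate 2, and 1.47 and 0.145 for replicate 3. Cyp1a1 had 5.30 CPM with vehicle and 4.28 CPM with MJ041 in WT libraries.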
